A study of Arabidopsis with 12 samples.

How the data were processed

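Gene expression was measured by RNA sequencing in the first and second rosette leaves of Arabidopsis thaliana Col-0, in 12 libraries that the labels place in 4 groups of 3 biological replicates: mock at 1 h, wound at 1 h, mock at 48 h and heat at 48 h. Per the labels' protocols, libraries were made with a standard TruSeq mRNA kit and sequenced as 100-base pairs of reads. STAR 2.7.10a, RSEM 1.3.1 and the TAIR10 build are named, without roles or settings, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here. Reads of a gene and an overlapping or antisense partner therefore could not be told apart.

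The authors deposited a gene table for each library with 36796 rows. Expected counts, which RSEM estimates by sharing reads between genes, were deposited by the authors without scaling, and 98.5% of them were whole within a tolerance of 0.005. TPM values in the same tables were scaled by the authors to the same total in every library, per the file headers. FPKM values were deposited beside them and were not used in any test. Length values per gene, per the file headers in bases and averaged over isoforms by RSEM, served only for a check of length. Gene names came from a table for assembly TAIR10.1, which differs in name from the authors' build, so no coordinates are printed. Of the IDs, 36632 matched, and the 164 that did not were all plastid or mitochondrial.

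Expected counts were rounded to whole numbers. Totals ranged from 8259483 to 15729755 per library, so that 3 counts, the most that an observed count of 0 allows, stand for 0.191 to 0.363 CPM (counts scaled to library size). Intervals at the 95% level and these floors cover counting error only. A gene at 0 in every library of a group is given as a bound against 3 counts over the group, and a gene with 1 to 3 counts over the group as a ratio with an exact binomial interval. No pair of replicates agreed within sampling noise.

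Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, all 12 libraries in a single fit, 8 residual degrees of freedom) and Benjamini-Hochberg adjusted p under 0.05. The default expression filter (minimum count 10, minimum total 15) left 18789 genes. The biological coefficient of variation was 22.7%. Standard errors are the absolute log2 fold change over the square root of F. Means and SDs of CPM are over 3 libraries, with TMM scaling. The comparisons were wound against mock at 1 h, heat against mock at 48 h, mock at 48 h against mock at 1 h, and the difference between the heat and wound effects. Wound and heat share no control library. The comparison of the mock groups shares libraries with both.

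A total of 35 gene lists, written from general knowledge, were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, at least 4 measured members), with estimated correlations and with fry. A list is said to be called at adjusted p under 0.05 by camera with the preset correlation, unless another test is named. Some other groupings of the same libraries gave as many calls by this test, as counted in the last paragraph. A call alone is therefore weak evidence. Camera compares a list with the other genes, while fry asks whether its own members moved. Of 551 list loci, 1 was dropped because its symbol disagreed with the reference. Named genes followed a rule: in each comparison the 8 largest rises and falls (5 for the mock and difference comparisons) among genes with adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between groups, then the smallest p in each list. Genes named outside it are examples or counts of list members, or are said to have been chosen after their values were seen. Design, lists, rule and most alternatives were fixed before the data were examined.

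On simulated counts, the test for wound against mock recovered 35.8% of genes changed 2-fold and 81.8% of genes changed 4-fold among 17917 genes. For heat against mock it recovered 32.8% and 77.3% among 18468 genes, and between the mock groups 34.3% and 80.3% among 17783 genes. False calls were 4.7%, 8.2% and 5.8% of the calls for wound, heat and the mock groups. Few genes were changed in each simulation (67 of them 2-fold and 66 4-fold), while 12200 passed in the real heat comparison. An adjusted p under 0.05 then takes a smaller raw p in the simulation, so its rates do not describe recovery in the real heat comparison.

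Replicate numbers from the labels were checked as pairs. Deviations from the group means correlated at 0.69, 0.58 and 0.6 between same-numbered mock and wound libraries at 1 h, and at no more than -0.08 between differently numbered ones. Deviations within a group sum to 0, so the latter values are no separate support. On the same-number values the numbers were taken to pair the 1 h libraries. At 48 h the correlations were 0, 0.09 and -0.03, and the numbers do not pair. A fit with a replicate block at 1 h was therefore added after seeing the data, and its values stand beside several wound results that it moves.

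Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), no filter or a stricter filter, only the groups compared, unrounded counts, organelle genes left out, replicate blocks, a 2-fold minimum and leaving out each library in turn. Heat against the 1 h mock was added after seeing the data.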

Results

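Transcript levels were compared in the first and second rosette leaves of Arabidopsis Col-0 plants after a wound (1 h), after a heat treatment (48 h) and in a mock group for each time, with 3 libraries per group. The title of the series places the experiment in a study of cell damage by heat, autophagy and cell expansion. Total expected counts were 8259483 to 14026499 in the 1 h mock libraries, 8778342 to 13639792 in the wound libraries, 9909720 to 15729755 in the 48 h mock libraries and 8971740 to 12523849 in the heat libraries. The first principal component held 67.6% of the variance and set the heat libraries apart from the other 9. The 4 RBCS genes, which encode the small subunit of Rubisco, took 5.51% ± 0.41 (SD, n = 3) of counts in the 48 h mock libraries and 0.663% ± 0.218 in the heat libraries. The 100 most abundant genes took 30.3% ± 0.453 and 13.7% ± 0.201 of counts in those groups, and TMM factors were 0.855 to 0.879 and 1.18 to 1.2.

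The first comparison asked which transcripts had changed 1 h after wounding. The jasmonate list had the highest median of the lists tested (2.33 in log2), though camera did not call it with an estimated correlation (adjusted p = 0.177). CYP94B3 (AT3G48520), which encodes a hydroxylase that inactivates jasmonoyl-isoleucine, rose from 0.301 ± 0.263 to 167 ± 53.1 CPM (SD, n = 3), a log2 fold change of 9.26 ± 0.55 (SE, adjusted p = 6.32e-05). AOS (AT5G42650), allene oxide synthase, rose from 258 ± 124 to 1845 ± 161 CPM (log2 2.84 ± 0.37, adjusted p = 0.00191), and AOC2 (AT3G25770), allene oxide cyclase, from 428 ± 140 to 1899 ± 176 CPM (log2 2.15 ± 0.28, adjusted p = 0.00192). RAP2.6 (AT1G43160), an ERF-family transcription factor, rose by 6.40 ± 0.42 in log2. AT3G63380 (log2 6.23 ± 0.64), the transcription factor gene MYB15 (AT3G23250, 6.22 ± 0.64) and JRG21 (AT3G55970, 6.0 ± 0.53) followed.

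The other large rises came from almost silent genes. ELI3-2 (AT4G37990) had 1 count over the mock libraries and 797 over the wound libraries, a ratio of 749.9 (95% interval 134.2 to 29660). RNS1 (AT2G02990), a ribonuclease gene, had 3 and 1880 counts, a ratio of 589.6 (201.5 to 2862). ILL5 (AT1G51780) had 1 and 354, a ratio of 333.1 (59.4 to 13190). Falls were small: WAK2 (AT1G21270), a wall-associated kinase gene with reads shared between genes in 5 libraries, fell from 56.3 ± 7.38 to 28.5 ± 2.24 CPM (log2 -0.98 ± 0.17, adjusted p = 0.00839). AT3G62550 (log2 -0.89), AT5G11250 (-0.84), AT5G63710 (-0.61), KICP-02 (AT3G50240, -0.61), AT2G42690 (-0.60), CSA1 (AT5G17880, -0.59) and AT1G63880 (-0.58) fell too. All of these but WAK2 lost the call without at least 1 library. AT5G63710 (adjusted p up to 0.121, without wound_1h replicate 1) and KICP-02 (up to 0.139, without wound_1h replicate 3) lost it in every such fit.

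**Figure D1:**
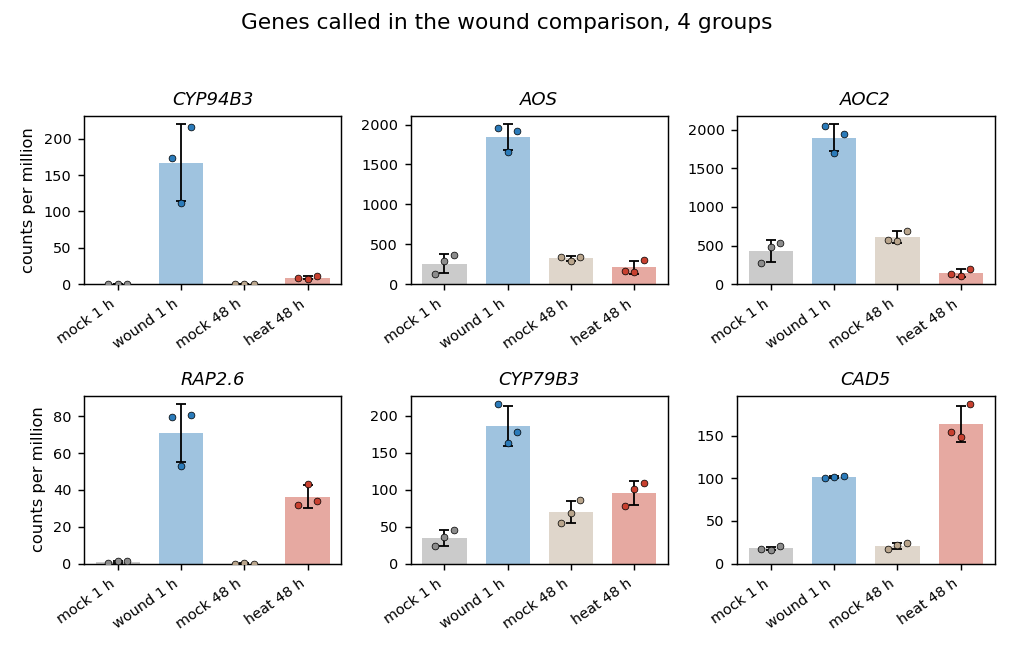
CPM (y axis, linear) of 6 genes in the 4 groups (x axis). Points are the 3 libraries of a group, bars their mean and whiskers 1 SD. Each gene is higher after wounding than in the 1 h mock group, and AOC2 is lower after heat than in the 48 h mock group.

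In total, 507 of 18789 genes passed (edgeR, adjusted p under 0.05), 496 higher and 11 lower, with 411 of the higher and 0 of the lower genes changed at least 2-fold. The 3 libraries of each group did not overlap for 13.3% of genes. Chance gives 10% for exchangeable libraries, but the 1 h libraries pair by number, so no chance value is given for this share. With the replicate block at 1 h, 953 genes passed, 869 higher and 84 lower, and 505 were among the 507. With a replicate block in the 1 h libraries alone, 2190 passed, 1345 higher and 845 lower (61.4% higher, against 97.8%), so the balance of rises and falls depends on the fit. The count was 329 without mock_1h replicate 1, 307 without wound_1h replicate 3 and 179 (177 higher, 2 lower) when only the 6 libraries at 1 h were fitted.

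Of 30 jasmonate genes measured, 14 rose after wounding and none fell (27 higher adjusted over the list alone), with a list median of 2.33 in log2. With the replicate block 22 rose. Beside AOS and AOC2 they included the lipoxygenase gene LOX3 (log2 3.73 ± 0.60), AOC3 (4.98 ± 0.73) and the repressor gene JAZ10 (3.17 ± 0.51). The list was called by camera (adjusted p = 1.38e-30, but adjusted p = 0.177 with an estimated correlation). Of 17 glucosinolate genes, 5 rose (6 over the list alone, 9 with the block, where 1 fell): MYB34 (2.32 ± 0.39), CYP79B2 (1.67 ± 0.21), CYP79B3 (2.41 ± 0.25), CYP83B1 (1.52 ± 0.26) and SUR1 (1.07 ± 0.20), of which the first 4 belong to indole glucosinolate synthesis or its control (camera adjusted p = 1.51e-08, adjusted p = 0.306 with an estimated correlation). Of 13 lignin and phenylpropanoid genes, 3 rose: CAD5 (AT4G34230, 2.52 ± 0.16), OMT1 (0.93 ± 0.16) and CCR2 (AT1G80820), which was at 0 counts in the mock group and at least 17.2-fold higher after wounding (camera adjusted p = 0.000229, adjusted p = 0.528 with an estimated correlation).

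Of 11 wound-induced regeneration factors, 3 rose (4 with the block). RAP2.6L (AT5G13330) rose by 2.84 ± 0.39, ERF114 (AT5G61890) went from 1 to 52 counts, a ratio of 48.9 (8.4 to 1969), and ANAC096 (AT5G46590) rose by 2.1 ± 0.44. This list alone kept its call with an estimated correlation (adjusted p = 1.04e-05 preset, 0.0313 estimated), though adjusted p = 0.102 with the estimated correlation and the replicate block. ANAC096 lost its call in 3 of the 6 fits without a library (adjusted p up to 0.135, without mock_1h replicate 1). Heat shock genes were also called (5 of 27 higher, 7 over the list alone, 10 with the block; median 0.75; adjusted p = 6.3e-10, 0.177 estimated), at low levels: HSP17.6A (AT5G12030) rose from 0.135 ± 0.0671 to 2.73 ± 1.36 CPM. GOLS1 (AT2G47180), a galactinol synthase gene, rose by 2.37 ± 0.25. In the oxidative stress list, called at adjusted p = 0.000229 (0.566 estimated), 2 of 18 rose (3 with the block), the glutathione transferase genes GSTU1 (2.28 ± 0.51) and GSTU4 (4.1 ± 0.67).

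Of 42 autophagy genes, none passed after wounding (edgeR, adjusted p under 0.05), with or without the block and adjusted over the list alone. The median was -0.05 in log2, and ATG4B (-0.24 ± 0.13, adjusted p = 0.626) had the smallest p. The list was not called (adjusted p = 0.477), but it was called as lower without mock_1h replicate 1 (0.0299) and without wound_1h replicate 3 (0.00887). DNA replication (median -0.26, 0 of 12 passed) and nuclear photosynthesis genes (median -0.17, 0 of 46) were called as lower (adjusted p = 0.00217 and 0.000787), with adjusted p = 0.566 and 0.924 with an estimated correlation. Early stress transcription factors (1 of 12 higher, RAP2.6) and abscisic acid genes (0 of 20, 4 with the block) were called as higher (adjusted p = 0.0102 and 0.0121, both 0.924 with an estimated correlation). The first call ended without mock_1h replicate 1 (0.943), wound_1h replicate 2 (0.164) or wound_1h replicate 3 (0.343), and the second without mock_1h replicate 2 (0.406) or wound_1h replicate 3 (0.343). Marker lists of epidermis, guard cell, phloem and xylem had medians of -0.22, 0.01, -0.04 and -0.04 and were not called. Epidermis was called as lower without wound_1h replicate 3 (0.018) and with a replicate block in the 1 h libraries alone (0.025).

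The other lists were not called after wounding in the fit of all libraries. Ethylene genes (0 of 16 passed, median 0.86, adjusted p = 0.115) were called as higher without mock_1h replicate 2 (0.0369) or 3 (0.0322) and with only the groups compared (0.0472), the unfolded protein response (1 of 15, ERDJ3A at 1.5 ± 0.23; 0.594) without wound_1h replicate 3 (0.00841), and carbon starvation (0.745) without wound_1h replicate 1 (0.00842). Ribosome biogenesis (median -0.06, 0.745) was called as lower without mock_1h replicate 3 (0.0322). Of 13 senescence genes PPH (0.94 ± 0.16) and ANAC019 (3.87 ± 0.71) rose. The list, not called (0.206), was called as higher with only the groups compared (0.0161) and with a replicate block in the 1 h libraries alone (0.0203). Of 19 salicylate genes EDS5 rose (1.78 ± 0.42, adjusted p = 0.0492; list 0.745), a call kept in 1 of the 6 fits without a library (up to 0.148, without mock_1h replicate 2).

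The second comparison asked what differed 48 h after heat. HSP17.6II (AT5G12020) was at 0 counts in the mock libraries and 279 ± 53.1 CPM after heat (SD, n = 3), at least 2897-fold higher, taking 3 counts as the most that 0 allows. HSP17.6C (AT1G53540) went from 1 to 22184 counts, a ratio of 17380 (3120 to 686700). ELI3-2 (633 ± 56.5 CPM, at least 6565-fold), NATA1 (AT2G39030, 356 ± 33.4 CPM, at least 3655-fold), TPS04 (AT1G61120, 329 ± 14.9 CPM, at least 3415-fold), AT2G38240 (158 ± 76.5 CPM, at least 1728-fold) and CYP82G1 (AT3G25180, 149 ± 17.2 CPM, at least 1564-fold) were at 0 in the mock group too. TPS04 and CYP82G1 act in the synthesis of the volatile homoterpene TMTT. AT1G48710, annotated as a pseudogene and with reads shared between genes in 3 libraries, rose at least 2246-fold.

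Among the genes with the largest falls, FT (AT1G65480), the mobile flowering signal, went from 318 to 2 counts, a ratio of 202.9 (55.7 to 1683). GER3 (AT5G20630), a germin-like protein gene, fell from 1254 ± 418 to 5.92 ± 4.44 CPM (log2 -7.75 ± 0.55, adjusted p = 4.54e-07). EXPA8 (AT2G40610), an expansin gene, fell from 134 ± 33.7 to 1.11 ± 0.489 CPM (log2 -6.86 ± 1.03). NAS1 (AT5G04950, -6.94 ± 0.51), which encodes a nicotianamine synthase, AT3G23880 (-6.57 ± 0.62) and MES18 (AT5G58310, -6.53 ± 0.54) fell as well. AT3G10185 went from 656 to 3 counts, a ratio of 279.0 (95.1 to 1357). CIB1 (AT4G34530), with reads shared between genes in 9 libraries, was at 0 after heat, at least 281.6-fold lower.

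In total, 12200 of 18789 genes (64.9%) passed, 6406 higher and 5794 lower, and 7764 were changed at least 2-fold. The libraries did not overlap for 72.9% of genes, where chance gives 10%. On the deposited TPM scale 13547 genes passed and 74.2% of them were higher, against 52.5% in the main fit, with the median of all genes shifted by 0.56 in log2. Against the 1 h mock group, 9537 of the 12200 (78.2%) passed in the same direction and 29 in the opposite direction. The lists called by camera all lost the call with an estimated correlation (adjusted p = 0.368 to 0.653).

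Protein-folding and defence genes rose together after heat. Of 27 heat shock genes 24 rose and 1 fell (HSP70-1, -0.67 ± 0.26), with a median of 6.83, or 5.73 with genes at 0 set to their bound (adjusted p = 4.03e-11, 0.368 estimated). HSP18.2 (AT5G59720) rose by 8.93 ± 0.27 and HSP70B (AT1G16030) by 7.16 ± 0.23. All 15 genes of the unfolded protein response rose (median 2.5; adjusted p = 3.71e-08, 0.368 estimated), among them ERDJ3A (AT3G08970, 5.09 ± 0.23) and BZIP60 (2.58 ± 0.22). Of 19 salicylate and pathogen defence genes 18 rose (median 4.72; adjusted p = 1.22e-06, 0.543 estimated), including PR1 (11.06 ± 1.22), ICS1, the isochorismate synthase of salicylate synthesis (3.48 ± 0.35), and CYP71A13 (AT2G30770), a camalexin enzyme gene that went from 3 to 8136 counts, a ratio of 2125 (727 to 10310). Of 18 oxidative stress genes 14 rose and 1 fell, the catalase gene CAT2 (-1.45 ± 0.27). The list was called at adjusted p = 0.00132 (0.543 estimated). GSTF6 (AT1G02930, shared reads in 3 libraries) rose by 7.78 ± 0.69, and AOX1D was at least 798-fold higher.

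Of 30 jasmonate genes 13 rose and 2 fell after heat, and the list was not called (adjusted p = 0.154), though it was called as higher with only the groups compared (0.0299). AOC3 rose by 6.41 ± 0.86 and CYP94B3 was at least 90.4-fold higher, while AOC2 (-2.11 ± 0.28) and AOC4 (-1.70 ± 0.25) fell. The regeneration list was not called by camera (adjusted p = 0.405) but was called as higher by fry (adjusted p = 1.42e-05). In it RAP2.6L rose by 7.86 ± 0.42, ANAC096 by 3.02 ± 0.46, ERF114 was at least 44.9-fold higher and PAT1 fell (-0.61 ± 0.25). Early stress transcription factors were called (8 of 12 higher; adjusted p = 0.0254, 0.653 estimated), but not without mock_48h replicate 1 (0.521) or any heat library (0.149, 0.222 and 0.199 without heat_48h replicate 1, 2 and 3). RAP2.6 had 1 count in the mock group and 1453 after heat, a ratio of 1139 (204 to 45010). Of 13 senescence genes 9 rose, among them SAG13 (AT2G29350, 12.22 ± 0.64) and the transcription factor gene JUB1 (6.61 ± 0.46), and NYC1, a chlorophyll b reductase gene, fell (-2.09 ± 0.14; list adjusted p = 0.0158, 0.543 estimated). Flavonoid and anthocyanin genes (10 of 13 higher, median 4.45, 4.02 with bounds; adjusted p = 0.00898, 0.651 estimated) and lignin genes (10 higher and 1 lower of 13; adjusted p = 0.00602, 0.543 estimated) rose too, CAD5 by 2.98 ± 0.16. Against the 1 h mock group the flavonoid list was not called (adjusted p = 0.0925).

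Nuclear photosynthesis genes fell: 39 of 46 were lower and 4 higher, with a median of -2.38 (adjusted p = 4.78e-11, 0.543 estimated). PETC (AT4G03280), the Rieske protein gene, fell from 2260 ± 172 to 260 ± 56.2 CPM (log2 -3.12 ± 0.18), PSBO2 (AT3G50820) by 2.66 ± 0.16 and PSAK (AT1G30380) by 2.81 ± 0.18. The 4 that rose were light-harvesting genes, LHCB1.1 (5.14 ± 0.35), LHCB2.1 (3.47 ± 0.31), LHCB2.2 (3.12 ± 0.34) and LHCB3 (1.07 ± 0.34). LHCB1 and LHCB2 copies share reads in up to 12 libraries, so sums were taken after their values were seen: the 5 LHCB1 genes together fell from 7415 ± 2590 to 3144 ± 832 CPM, and the 3 LHCB2 genes rose from 61.2 ± 23 to 515 ± 206 CPM. Aquaporins fell (12 lower, 2 higher of 17, median -1.48; adjusted p = 0.00454, 0.543 estimated), PIP1;5 (AT4G23400) by 2.01 ± 0.16. The 2 that rose were PIP2;5 (1.40 ± 0.24) and PIP2;3 (1.58 ± 0.51), the latter with reads shared in 12 libraries. Markers of other cell types moved apart: 6 of 6 xylem genes were higher (median 0.60), while 4 of 6 epidermis genes were lower and 1 higher (median -1.87). Of 5 guard cell genes 3 were lower and 1 higher, and of 6 phloem genes 2 were lower. Camera called none of these lists (adjusted p = 0.108, 0.0983, 0.464 and 0.235). Fry called xylem as higher (adjusted p = 0.000398) and epidermis (0.000306), guard cell (0.015) and phloem (0.000835) as lower. Against the 1 h mock group only 3 of 6 xylem genes were higher and 0 lower (median 0.46). There 5 of 6 epidermis genes were lower and 0 higher (median -2.36), and camera called the epidermis list as lower (adjusted p = 0.00411).

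**Figure D2:**
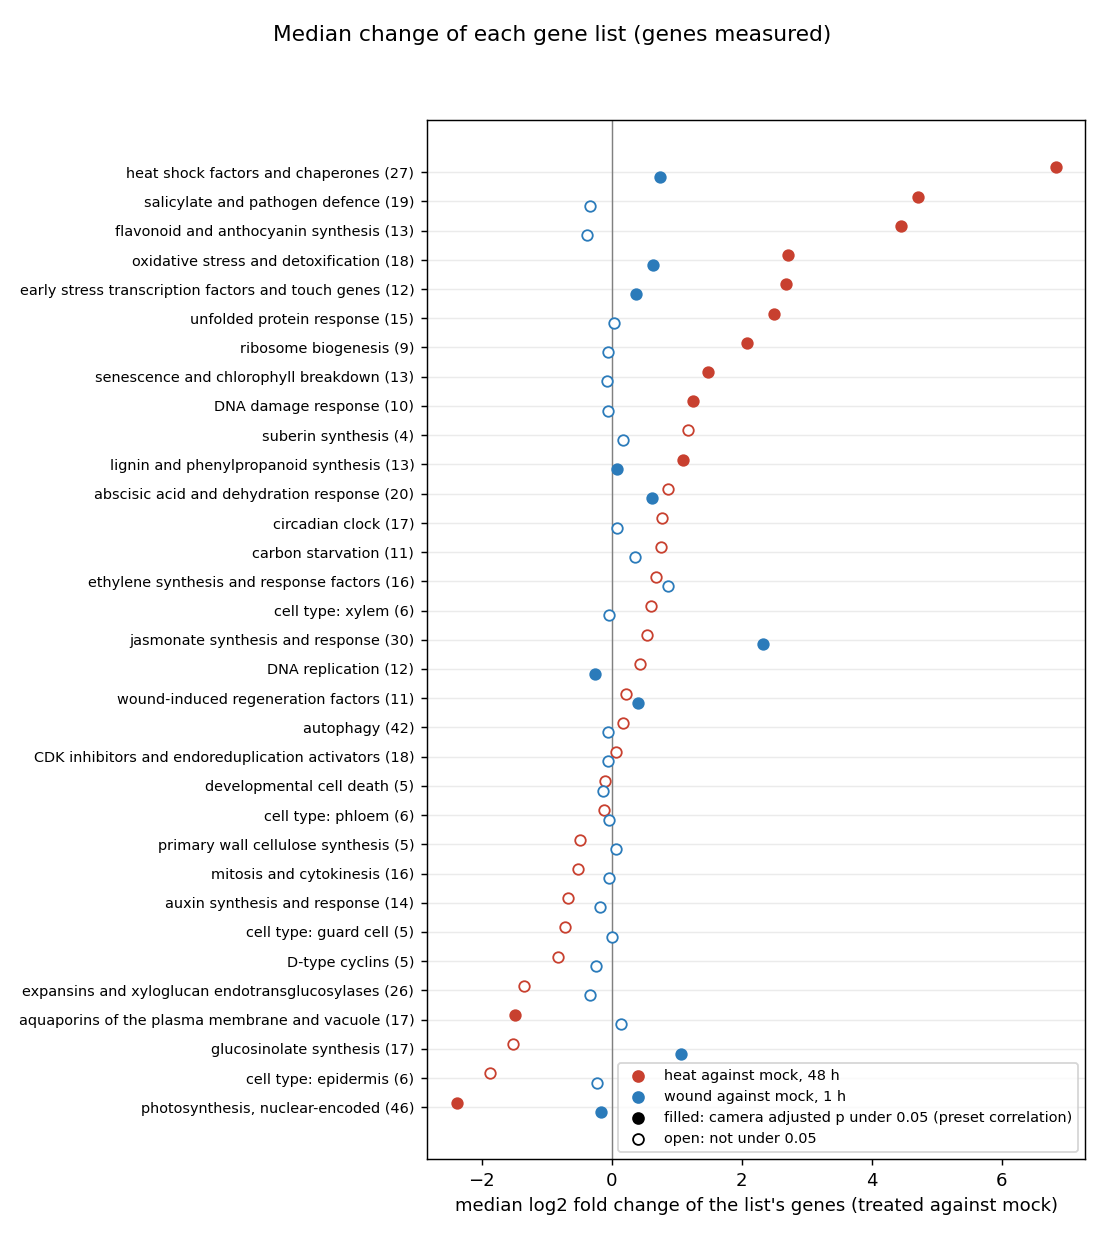
Median log2 fold change (x axis) of the measured genes of each list with at least 4 of them (y axis, number measured in brackets), after heat (red) and wounding (blue). Filled points mark lists called by camera with the preset correlation. Heat shock genes had the highest median after heat (6.83) and jasmonate genes the highest after wounding (2.33).

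Wall-expansion genes moved both ways. Of 26 expansin and xyloglucan endotransglucosylase genes 14 fell and 5 rose, and the list was not called by camera (median -1.35, adjusted p = 0.0983). Fry called it as lower (adjusted p = 0.00075). Camera called it as lower against the 1 h mock group (0.0472), with only the groups compared (0.0485) and with a replicate block within each time (0.0408). EXPA11 (AT1G20190) fell by 5.28 ± 0.53 and XTH7 (AT4G37800) by 3.87 ± 0.49. The rises were XTH18 (AT4G30280, 7.28 ± 0.79), XTH19 (3.32 ± 0.60), XTH23 (8.22 ± 1.43), XTH24 (7.33 ± 0.99) and EXPA4 (0.98 ± 0.31). After wounding XTH18 missed the threshold (2.39 ± 0.61, adjusted p = 0.0715) but passed with the replicate block (2.55, adjusted p = 0.00785). Of 5 primary wall cellulose genes 3 fell after heat, CESA3 by 0.53 ± 0.15, though on the TPM scale CESA3 was at 0.054. The cellulose list was not called (adjusted p = 0.342).

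Camera called no cell-cycle list as a whole, while single members changed after heat. Fry called DNA replication genes (adjusted p = 0.000724) and CDK inhibitors and endoreduplication activators (0.0176) as higher, but not mitosis genes (0.155). Of 12 DNA replication genes 7 rose, among them PCNA1 (0.79 ± 0.14) and MCM4 (0.81 ± 0.15; list adjusted p = 0.0983). Of 16 mitosis genes CYCB1;1 rose (2.35 ± 0.36) and CYCB2;4 (-0.97 ± 0.28), KNOLLE (-1.12 ± 0.23) and AUR1 (-0.96 ± 0.34) fell (adjusted p = 0.342). Against the 1 h mock group 14 of the 16 fell, 1 rose and the list was called (adjusted p = 0.00411). Among 18 CDK inhibitors and endoreduplication activators 7 rose and 7 fell (adjusted p = 0.853). SMR7 (AT3G27630) rose by 4.59 ± 0.58, SMR4 by 3.35 ± 0.60 and KRP3 by 3.24 ± 0.67, and KRP1 fell by 1.66 ± 0.29. SMR5 had 1 count in the mock group and 70 after heat, a ratio of 54.9 (9.53 to 2197). The DNA damage list was called (8 of 10 higher, median 1.25; adjusted p = 0.00898, 0.543 estimated), with XRI1 (AT5G48720) at 2.22 ± 0.20. Ribosome biogenesis genes were called as well (9 of 9 higher, median 2.09; adjusted p = 0.00162, 0.543 estimated), but none of the 9 differed between heat and the 1 h mock group (median 0.35; list adjusted p = 0.321). They were lower in the 48 h than in the 1 h mock group, and both comparisons use the 48 h mock libraries.

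Of 42 autophagy genes 11 rose and 6 fell after heat, 25 did not pass, and the list was not called (median 0.18, camera adjusted p = 0.349). Over all genes tested 64.9% passed, a larger share than in this list. NBR1 (AT4G24690), a selective autophagy receptor gene, rose from 260 ± 25 to 732 ± 60.1 CPM (log2 1.49 ± 0.14, adjusted p = 3.91e-06). ATG8B (AT4G04620, 1.36 ± 0.17), ATG18A (1.32 ± 0.19), ATG7 (AT5G45900, 1.28 ± 0.18), ATG1A (1.18 ± 0.21), ATG8A (1.16 ± 0.29), ATG14A (0.94 ± 0.19), ATG18B (0.88 ± 0.24), ATG18H (0.69 ± 0.20), VPS15 (0.58 ± 0.18) and ATG9 (0.37 ± 0.12) rose. ATG8F (-0.95 ± 0.17), ATG18G (-0.73 ± 0.20), ATG8C (-0.68 ± 0.18), ATG1C (-0.60 ± 0.14), ATG4B (-0.51 ± 0.13) and ATG14B (-0.51 ± 0.16) fell. Against the 1 h mock group 18 rose and 1 fell and the list was called (median 0.40, adjusted p = 0.00588), with ATG8F at 0.053 and ATG18G at 0.045. ATG4B (0.125) and ATG14B (0.06) were above 0 on the TPM scale. ATG14B lost its call in 3 of the 6 fits without a library (adjusted p up to 0.0684, without heat_48h replicate 3), ATG9 in 2 (up to 0.0829, without mock_48h replicate 2) and VPS15 in 1 (0.0528, without mock_48h replicate 2).

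**Figure D3:**
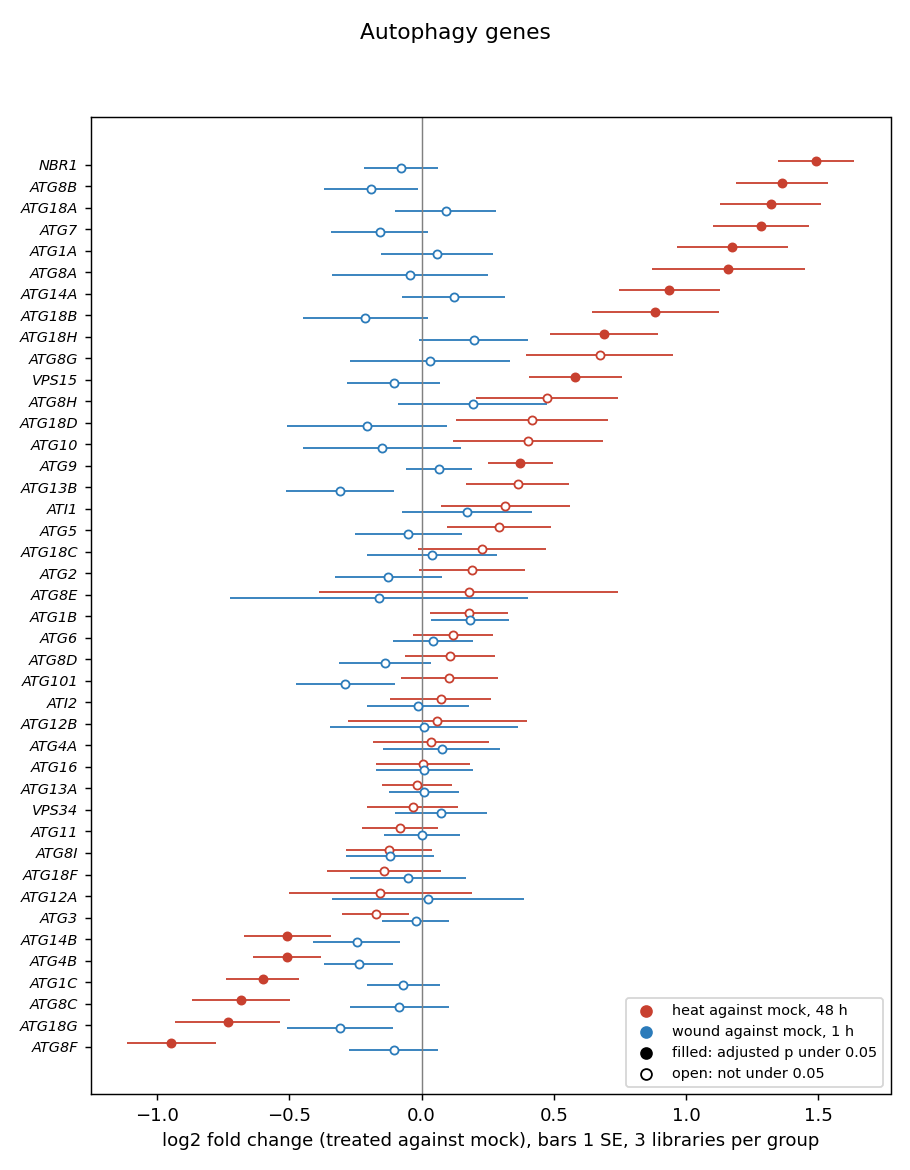
Log2 fold change (x axis, whiskers 1 SE, 3 libraries per group) of the 42 autophagy genes measured (y axis), after heat (red) and wounding (blue). Filled points have adjusted p under 0.05: 17 after heat, from ATG8F (-0.95) to NBR1 (1.49), and 0 after wounding.

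Clock genes changed in both directions after heat: 8 of 17 rose and 7 fell. The list was not called as a whole by camera (adjusted p = 0.453), while fry called it as higher (adjusted p = 2.08e-05). With the 1 h mock group as control 9 rose and 3 fell (median 1.61, not called), and the list was called as higher in the 48 h than in the 1 h mock group. CCA1 (AT2G46830) rose from 0.602 ± 0.134 to 95.5 ± 8.97 CPM (log2 7.27 ± 0.28, adjusted p = 2.51e-08), with LHY (6.84 ± 0.39), RVE8 (3.76 ± 0.44), LNK2 (3.63 ± 0.14), LNK1 (3.34 ± 0.40), RVE1 (2.29 ± 0.27) and PRR7 (2.14 ± 0.32), while PRR9 went from 1 to 280 counts, a ratio of 219.4 (39.1 to 8697). TOC1 (-1.41 ± 0.15), ELF3 (-1.50 ± 0.11), ELF4 (-1.51 ± 0.26), FKF1 (-1.85 ± 0.42), BOA (-1.81 ± 0.27), LUX (-0.80 ± 0.26) and CDF1 (-1.62 ± 0.49) fell. The hour of harvest is not given in the labels. In the wound comparison 0 of the 17 passed (adjusted p of the list 0.965).

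**Figure D4:**
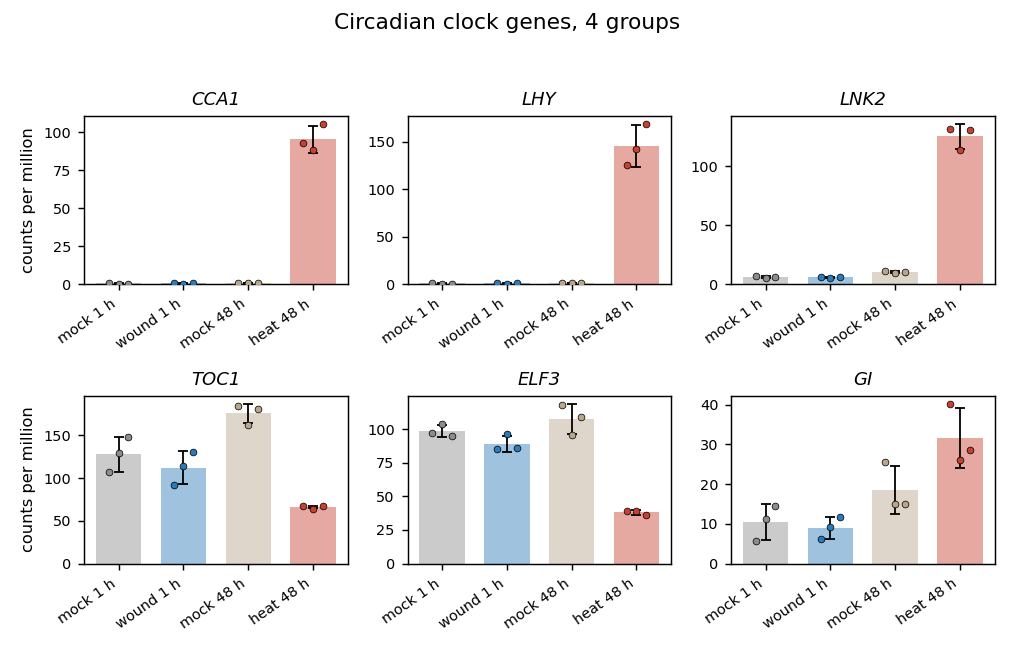
CPM (y axis, linear) of 6 clock genes in the 4 groups (x axis). Points are the 3 libraries of a group, bars their mean and whiskers 1 SD. CCA1 reached 95.5 CPM after heat against 0.602 in the 48 h mock group, and ELF3 was lower after heat.

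The remaining lists were not called by camera after heat. Among them fry called auxin (adjusted p = 0.0176), ethylene (0.0467) and suberin genes (0.000148) as higher and D-type cyclins as lower (0.0176). Among 17 glucosinolate genes 9 fell, MYB28 (AT5G61420) by 3.64 ± 0.32, and 4 rose, CYP79B2 by 2.43 ± 0.22 (median -1.51, adjusted p = 0.448). The balance turned against the 1 h mock group, with 8 higher and 4 lower (median 0.50, not called), and the list was called as higher in the 48 h than in the 1 h mock group. Among 20 abscisic acid genes 9 rose and 3 fell (0.349), among 16 ethylene genes 3 rose and 1 fell (0.345), and among 14 auxin genes 4 rose, GH3.3 (AT2G23170) by 7.11 ± 0.51, and 6 fell (0.772). Among 5 D-type cyclin genes 2 rose and 3 fell, CYCD1;1 by 3.48 ± 0.25 (0.569). Of 11 carbon starvation genes 3 rose and 1 fell (0.781), of 4 suberin genes 2 rose (0.345) and of 5 developmental cell death genes none passed (0.943). Compared with the 1 h mock group, 1 carbon starvation gene rose and 2 fell, 1 suberin gene rose and 2 fell, and 2 cell death genes rose.

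The third comparison asked how the mock groups differed between 1 h and 48 h. Ribosome biogenesis genes were lower at 48 h, 9 of 9 (median -1.62; adjusted p = 1.2e-08, 0.528 with an estimated correlation), with APUM24 (AT3G16810) at -1.62 ± 0.22. Glucosinolate genes were higher, 9 of 17 (median 1.09; adjusted p = 2.67e-06, 0.528 estimated), with CYP79B2 at 1.47 ± 0.21. AAP2 (AT5G09220), an amino acid permease gene, was higher by 3.62 ± 0.37, NAS1 by 3.32 ± 0.38, AT1G76960 by 4.22 ± 0.55, CAF1a (AT3G44260) by 3.3 ± 0.71 and NUDT21 (AT1G73540) by 3.27 ± 0.71. GA3OX1 (AT1G15550), a gibberellin oxidase gene (-4.80 ± 1.28), AT4G28900 (-4.62 ± 1.04), CYP94C1 (AT2G27690, -4.35 ± 0.94), the invertase gene ATBFRUCT1 (AT3G13790, -3.90 ± 0.67) and EXPA16 (AT3G55500, -3.85 ± 0.51) were lower. CAF1a, NUDT21, GA3OX1, AT4G28900 and CYP94C1 lost the call without some library, with adjusted p up to 0.0516 (mock_48h replicate 3), 0.0542 (mock_1h replicate 2), 0.13 (mock_1h replicate 2), 0.0674 (mock_48h replicate 2) and 0.0561 (mock_48h replicate 3).

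Between the mock groups 5 of 42 autophagy genes were higher at 48 h: ATG8F (1.00 ± 0.17), ATG18G (0.78 ± 0.20), ATG8I (0.60 ± 0.17), NBR1 (0.52 ± 0.14) and ATG4B (0.50 ± 0.13; list median 0.31, adjusted p = 0.000742, 0.769 with an estimated correlation). Photosynthesis (4 of 46 higher, 0 over the list alone; adjusted p = 0.00021, 0.769 estimated) and clock genes (2 of 17 higher, ELF4 and LNK2; adjusted p = 0.000742, 0.518 estimated) were also called as higher. Mitosis genes (4 of 16 lower, 7 over the list alone; adjusted p = 1.06e-05, 0.528 estimated), flavonoid genes (5 of 13 lower; 0.0132, 0.769 estimated) and epidermis markers (2 of 6 lower, PDF1 and CER1; 0.0278, 0.616 estimated) were called as lower. The flavonoid call ended without mock_1h replicate 1 (0.152) and the epidermis call without mock_1h replicate 3 (0.122). ELF4 kept its call in 3 of the 6 fits without a library (adjusted p up to 0.094, without mock_1h replicate 2). Jasmonate genes (3 of 30 lower, adjusted p = 0.205) were called as lower without mock_1h replicate 1 (2.47e-07) or mock_48h replicate 3 (0.0428). Other lists gained a call as lower without mock_1h replicate 1 (aquaporins 0.0224, carbon starvation 0.0174) or mock_1h replicate 2 (lignin 0.0486, suberin 0.0471). Without mock_48h replicate 1, abscisic acid genes (0.0338) and early stress transcription factors (0.021) gained a call as higher. In total 2803 genes passed, 1406 higher and 1397 lower, of which 1187 were changed at least 2-fold. The count was 931 without mock_1h replicate 2, 963 without mock_48h replicate 2, 899 without mock_48h replicate 3 and 1324 when only the 6 mock libraries were fitted. On the TPM scale 22% of 3124 calls were higher, against 50.2%, with a median shift of -0.13. TCH4, a touch-induced wall enzyme gene chosen after its values were seen, was at 1.58, 564.5 and 196.4 CPM in mock_1h replicates 1, 2 and 3.

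The fourth comparison set the heat effect against the wound effect. Of the 496 genes higher after wounding, 329 (66.3%) were also higher after heat, where independent lists of these sizes would share 169.1, and 46 were lower after heat, against 153 for independent lists. Across the 18789 genes, which are not independent replicates, the fold changes correlated at r = 0.346 (Spearman 0.364). Single wound and heat libraries, each set against the mean log2 CPM of its mock group, gave 0.218 to 0.399 over 9 pairings. That range leaves out the spread of the mock libraries. The effects differed for 8497 genes, 4174 with a higher and 4323 with a lower heat effect, and on the TPM scale for 10806, 75.7% of them with a higher heat effect against 49.1%. Treatment and time differ together in this comparison. Effects differed for 45.2% of all genes tested. Above that share were 41 of 46 photosynthesis genes (37 with a heat effect below the wound effect), 15 of 15 of the unfolded protein response and 9 of 9 of ribosome biogenesis. Below it were 11 of 42 autophagy genes (9 with a heat effect above the wound effect), 2 of 11 regeneration factors and 2 of 16 ethylene genes.

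Among the genes named for this difference, CSLG2 (AT4G24000) was at 0.373 ± 0.376 CPM in the 1 h mock, 0.038 ± 0.0659 in the wound, 0 in the 48 h mock and 121 ± 17 in the heat libraries, and PNP-A (AT2G18660) at 0.322 ± 0.249, 0, 0.0248 ± 0.0429 and 106 ± 43.8 CPM. AT3G02480, LEA7 (AT1G52690) and NADP-ME1 (AT2G19900) reached 34.7 ± 28.4, 41.9 ± 46.6 and 15.1 ± 7.96 CPM after heat, from 0 in the 48 h mock. Their differences lost the call without mock_1h replicate 1 (adjusted p = 0.301, 1 and 1). AT4G29700 went from 15.1 ± 8.93 to 65.3 ± 13.5 CPM after wounding and from 39.4 ± 14.3 to 0.941 ± 0.418 after heat. AT5G62360 went from 18.8 ± 7.47 to 110 ± 42.3 and from 17.7 ± 8.45 to 0.663 ± 0.0966 CPM. GER3, CIB1 and FT, named above for their falls after heat, were at 1267 ± 327, 13.5 ± 12.5 and 1.91 ± 1.48 CPM in the wound group and at 1762 ± 365, 19.8 ± 16.8 and 2.17 ± 1.71 CPM in its mock group.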

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

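Genes were picked out here where the heat and wound effects were called with opposite signs, a choice that all but ensures that a test of the difference passes (edgeR). Of 47 such genes 46 were higher after wounding and lower after heat, as follows from 496 of the 507 wound calls being rises. This balance holds for the fit without a replicate block and was not counted with one. The members of the gene lists among them were AOC2 and MYB34. For AOC2, a jasmonate synthesis gene, the effect was 2.15 ± 0.28 after wounding and -2.11 ± 0.28 after heat, a difference of -4.25 ± 0.40 in log2 (adjusted p = 1.46e-05). For MYB34, a regulator of indole glucosinolate synthesis, the effects were 2.32 ± 0.39 and -2.16 ± 0.40, a difference of -4.47 ± 0.56 (adjusted p = 8.49e-05). The times of sampling differ between the comparisons as well as the treatments. Groups of 3 libraries were not tested for outlying samples.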

How the results depend on the processing

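Alternatives with replicate blocks other than the planned one, and heat against the 1 h mock, were chosen after seeing the data. For wound against mock, the counts of genes were 179 with only the groups compared, 307 to 516 leaving out single libraries, 640 with the planned replicate block over 12 libraries, 1044 (922 higher, 122 lower) with a replicate block within each time, 953 with a replicate block at 1 h and 2190 (1345 higher, 845 lower) with a replicate block in the 1 h libraries alone. For heat against mock they were 11085 to 11549 leaving out single libraries, 7764 with a 2-fold minimum and 11179 against the 1 h mock. For the mock groups they were 1324 with only the groups compared, 899 to 3004 leaving out single libraries and 1187 with a 2-fold minimum. For the difference of effects they were 7379 to 8307 leaving out single libraries. The correlation of wound and heat fold changes was 0.222 without a filter on low counts, 0.487 with only the groups compared and 0.287 to 0.397 leaving out single libraries. The other settings, DESeq2 and limma-voom among them, moved these counts by less than 1.5 times. Fewer libraries and genes enter a fit of only the groups compared; for the other changes the cause was not tested.

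Called lists numbered 1 of 33 after wounding with an estimated correlation and 5 with fry (9 to 12 leaving out single libraries), 0 and 25 after heat (11 to 12), and 0 and 4 between the mock groups (7 to 10). Among results called in either fit, directions after heat were reversed for the auxin list under fry (adjusted p = 0.0176), for CESA3 (0.054), ATG4B (0.125) and ATG14B (0.06) on the TPM scale, and for ATG8F (0.053) and ATG18G (0.045) against the 1 h mock. Medians of lists not called by camera in either fit also changed sign against the 1 h mock: glucosinolate (-1.51 to 0.50), suberin (1.18 to -0.80), carbon starvation (0.76 to -0.56), regeneration (0.22 to -0.01) and cell death (-0.10 to 0.72). Heat against the 1 h mock differs from heat against the 48 h mock only in the control group. The sign changes there therefore come from the difference between the mock groups (0.999 in log2 for ATG8F). The TPM scale raised the median of all genes after heat by about as much as CESA3, ATG4B and ATG14B fell in the main fit. Their reversals on that scale are therefore no evidence of a change particular to these genes. Why the scales differ, and why the auxin list was reversed under fry, was not tested. The replicate block at 1 h brought XTH18 (2.55), PIP2;3 (1.84) and RD20 (3.08) past the threshold after wounding and ended no named call. At 48 h the numbers do not pair the libraries. In simulations with few genes changed, those changed 1.5-fold were recovered in 4.5% of cases for wound and 7.5% for heat. The real heat comparison, with far more genes changed, is not described by that share.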

Other observations

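The bounds for gene length, clock-controlled genes and thinned counts were written before those results were seen, while those for cell type markers, scaling, shared deviations and regrouped libraries were chosen after the result was seen.

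Transcripts of a retrotransposon family accompanied the heat shock genes. The 8 loci taken from general knowledge as copies of the heat-responsive Copia element ONSEN, all annotated as pseudogenes, were put together after AT1G48710 had been seen among the largest rises. Together they had 5 counts in the 1 h mock, 4 in the wound, 1 in the 48 h mock and 18379 in the heat libraries, 453 ± 89.4 CPM (SD, n = 3) after heat, a ratio of heat to 48 h mock of 14400 (95% interval 2585 to 568900). All 8 passed in the heat comparison, with adjusted p from 5.9e-07 to 0.000325. AT1G48710 (212 ± 41.6 CPM) and AT1G11265 (78.8 ± 18.8 CPM) were the most abundant. Reads are shared between the copies, so the sum is firmer than any copy. Pseudogenes together took 0.184% ± 0.0114 of counts after heat and 0.0877% ± 0.00551 in the 48 h mock group.

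The first pattern is the fall of nuclear photosynthesis genes after heat. A smaller share of mesophyll cells by itself would raise the markers of every other cell type alike. The xylem median lay 2.47 above the epidermis median in log2 (2.32 to 2.69 over 9 pairings of single libraries), so a smaller share alone does not account for the markers. The lists hold 5 or 6 genes, and 64.9% of all genes changed after heat, markers among them. A smaller share beside such changes therefore stays open. Scaling moves all genes of a library alike, and the photosynthesis median lay -2.45 from the median of all genes tested (-2.94 to -1.89). After the median of genes of the same length was taken off, it was -2.48 (-3.02 to -1.87), so length bias does not account for it either. A response of the leaf to heat, also open to differences at harvest, remains a hypothesis, since the pattern was found and tested on the same data.

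The second pattern is the rise of morning and fall of evening clock genes after heat, 8 of 8 morning genes higher and 6 of 8 evening genes lower, with CDF1, which fell, in neither set, and with 3 of 17 clock genes lower against the 1 h mock group. Scaling would move both sets one way, but the evening median lay -1.52 from the median of all genes, while the morning genes rose. If the heat leaves had been harvested in the morning and the mock leaves at another hour, other clock-controlled genes would have moved alike. Of 9 such genes, 5 passed in that direction (COL1, GRP7, PRR3, COR27 and AT4G33980). RVE2, listed as a morning gene, fell by 3.13 ± 0.29. The morning genes EPR1 (AT1G18330, 0.24 ± 0.56) and COL2 (0.78 ± 0.49), at 3.21 and 4.67 CPM after heat, leaned upward without passing. The evening gene CCR1 (AT4G39260, 0.71 ± 0.38) leaned upward too, against the prediction, without passing. The count of 5 is the bound set beforehand against an hour of harvest. It cannot decide, since genes at low levels that missed the threshold count as not moved. The phases came from general knowledge and the labels give no hour. An hour of harvest, in part or whole, stays open beside an effect of heat on the clock, which was not tested.

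The third pattern is that same-numbered mock and wound libraries at 1 h deviate together. Among 1838 genes of at least 100 CPM the lowest same-number correlation was 0.826, and the highest between different numbers 0.023. After every library was thinned to 8259474 counts the same-number correlations were 0.827, 0.848 and 0.865, all above the bound set beforehand. Equal totals thus left the shared deviations in place. This argues against the number of counts itself as their source in these abundant genes. Total counts fall from replicate 1 (14026499 in mock, 13639792 in wound) to replicate 3 (8259483 and 8778342) in both groups. A batch of plants or handling shared by replicate number may account for the pattern. Whatever in the handling set the depth follows the same numbers and cannot be told apart from such a batch, since the labels do not give what was shared.

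Other groupings of the same libraries were counted. With 10 splits of 6 libraries no share can fall under 0.05. The real split gave 179 genes for wound against mock, 12332 for heat against mock and 1324 for the mock groups, and the highest other split gave 0 in each. In each case 1 split, the real one, reached its count. Of the 4 splits that part the 3 pairs at 1 h, the highest other also gave 0. For lists, 3, 5 and 7 of the 10 splits, the real one included, gave as many as the real 12, 14 and 8, with 16, 18 and 14 in the highest other split. Those other splits had 0 changed genes, so the number of lists called does not set the real grouping apart. For the difference of effects, 7 of 100 relabellings within each time, the real one included, gave at least the real 8497 genes, with 10154 in the highest other. All 7 kept the heat and mock libraries at 48 h whole and so carry the whole heat effect, as did 8 of the 100. Relabellings that mixed those libraries gave at most 0 genes. The share of relabellings is therefore no measure of chance for this count, and whether chance can be excluded stays open.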
